A study of Homo sapiens with 4 samples.

How the data were processed

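Single-cell RNA sequencing was done on H7 human embryonic stem cells taken toward cardiac mesoderm. Mesoderm was induced with 2 µM CHIR99021 for 24 h, Activin A, BMP4 and FGF2, and IWP2, which blocks the secretion of WNT ligands, was given at 5 µM. Ascorbic acid (65 µg/ml) was in the medium of the day-4 cultures from day 2 on. There were 4 libraries: day 2, and day 4 after 0, 12 or 48 h of IWP2 counted back from the harvest (the 12 h dose followed 36 h without it). Each group had 1 library. Per the labels, the cells were frozen, thawed and sorted as DAPI-negative live singlets before about 6000 were loaded per 10x Chromium lane.

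The deposited matrices hold UMI counts per gene and barcode, made by the authors with Cell Ranger 3.0.2 per the file headers and the submitters' processing notes. Every stored value was a whole count over 33538 genes. The genome build and annotation were not given in the sources used here, so genes were taken by the symbols and gene IDs of the files and no coordinates were used. The matrices held 2656 (day 2), 2937 (0 h), 4099 (12 h) and 3084 (48 h) barcodes.

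Barcodes with under 1000 genes or over 20% mitochondrial UMIs were left out. These were 32.6% of the barcodes at day 2, 14.2% at 0 h, 16.6% at 12 h and 21.4% at 48 h. Their median mitochondrial shares were 84.9, 88.4, 85.2 and 78.5% of UMIs, the profile of damaged cells. Doublets were scored with the Scrublet implementation of scanpy 1.11.5 at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 0.0877% of cells at 12 h and 0.371% at 48 h, under the 0.5% set as its minimum, so the cells with the highest scores were removed there up to the expected share (112 and 60 cells). At day 2 and 0 h the automatic threshold removed 29 and 14 cells. The cells used numbered 1761, 2506, 3307 and 2363, with 42068440, 37201604, 39242751 and 42243028 UMIs and medians of 23084, 13882.5, 10809 and 15704 UMIs per cell.

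For each library the UMIs of the cells used were summed per gene and divided by the library total to give counts per 1000000 UMIs (CPM). CPM carry exact Poisson intervals, ratios exact conditional binomial intervals and shares of cells Clopper-Pearson intervals, all at 95%. These intervals cover counting error only: with 1 library per group no spread between cultures could be estimated, so no test between groups was made and no p-value is given. Counts of genes at least 2-fold apart (among genes at 50 CPM or more in the higher library) and the medians of gene lists are given as a description of these libraries. A ratio against 0 counts was computed against a floor of 3 counts per library and is written as at least that fold. Such a value rests on the floor, and the low end of its 95% interval can lie below it. Poisson counts, without any spread between cultures, were simulated at the depth of each comparison. In them 100 of 100 genes set 3-fold apart and 0 of 100 genes set 1.5-fold apart came out at least 2-fold apart. So did 0 of the unchanged genes (2638 to 2740 per comparison). The intervals held the true ratio for 95.0 to 95.6% of genes. These simulations check the calculation only and give no rate of false calls between cultures.

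The 5 comparisons, the thresholds, the 28 gene lists, the markers of the 8 cell classes and the rule for naming genes were set before the data were examined. Genes at 50 CPM or more were ranked by the interval end nearest to 0, and the first in each direction were named: 12 each way for 48 h against 0 h and for both comparisons with day 2, and 8 each way for 12 h against 0 h and 48 h against 12 h. Mitochondrially encoded genes, ribosomal protein genes, XIST, TSIX, Y-linked genes and clone-based, uncharacterised or antisense names were left out. The rule also allowed list members to be named, and those given as examples were chosen after their values were seen. A list was summarised by the median log2 ratio of its members at 5 CPM or more in either library. The median was placed among those of 10000 random lists matched on 20 bins of expression. The lists were WNT feedback targets, WNT ligands and R-spondins, secreted WNT antagonists, pluripotency, primitive streak and mesendoderm, cardiac mesoderm and progenitors, lateral plate mesoderm, cardiac contractile, presomitic and paraxial mesoderm, HOX, definitive endoderm, endothelium and blood, amnion and surface ectoderm, neural ectoderm, epicardium and juxtacardiac field, epithelium and cell transition, BMP response, FGF and ERK response, Notch, retinoic acid, S phase, G2 and M phase, hypoxia and glycolysis, immediate early and heat shock, p53, unfolded protein, cholesterol synthesis, and extracellular matrix. Some genes stand in more than 1 list. Results for some single genes are not reported here.

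Cells of all 4 libraries were clustered together in scanpy on counts scaled to 10000 per cell and log-transformed, 2000 variable genes without mitochondrial, ribosomal protein and cell-cycle genes, 30 principal components (scikit-learn 1.9.0), 15 neighbours (umap-learn 0.5.12) and the Leiden method at resolution 0.5 (igraph 0.11.9). No batch correction was used, since library and group coincide. A cluster took a class name when at least 3 markers of the class were detected in 10% of its cells and 1.5-fold above the other cells, more than for any other class. After the data had been seen, this rule was extended: the name was dropped where the 10 leading genes of a cluster held more members of another class than of its own. The day-4 cells were also clustered, after the data had been seen, without the 648 genes at least 2-fold apart between any pair of day-4 libraries, so that the grouping of cells did not rest on these genes. The clusters were still named from the full marker lists, which hold genes left out of the clustering, such as NKX2-5 and PAX6. Class shares therefore still rest on such genes through the names. Comparisons within clusters used clusters with at least 50 cells in both libraries and genes at 10 CPM or more.

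Shares of cells with a UMI of a marker were computed in cells thinned to 5000 UMIs (2, 33, 62 and 19 shallower cells left out), beside the share without thinning and the share in a class that should lack the gene. There were 14 markers chosen before the data were examined, and MYH6, SOX10 and HHEX were added after. The ratios at 12 and 48 h share the 0 h library, so their correlation across genes was set beside that of 100 Poisson simulations with no difference between libraries.

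Alternatives tried were the scaling factors of edgeR 4.0.16 (TMM) and DESeq2 1.42.0 in R 4.3.3, used for scaling only, all barcodes, doublets kept, the mean over cells, totals without mitochondrial and ribosomal protein genes, mesoderm cells only, minimums of 20 and 100 CPM, other minimums for list members, a resolution of 1.0, clustering of thinned cells, and a minimum of 2000 genes per cell. Mesoderm cells there were all cells outside the pluripotent-like, neural ectoderm-like and definitive endoderm-like classes. The unnamed clusters thus stayed in, among them a SOX10-led one and a mostly day-2 one with POU5F1 and SOX2 raised. Numerical work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with matplotlib 3.10.9 for the plots and 1 as random seed. Transcript lengths, used only for the test of short transcripts, came from GENCODE matched by gene ID, and the build behind the files may differ from it.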

Results

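The day-4 libraries differed in the levels of cardiac muscle genes and of genes of other lineages. After 48 h of the WNT inhibitor, sarcomere genes and some cardiac transcription factor genes, such as NKX2-5, were higher than without it, while HOX genes and targets of WNT signalling were lower. After 12 h, WNT targets were already lower but the sarcomere genes as a group were not higher. Each group had 1 library, so the values describe these libraries and their intervals cover counting error alone.

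From day 2 to day 4 without inhibitor, genes of the primitive streak gave way to genes of the heart and lateral plate. Ascorbic acid was added to the medium from day 2 on, so its effect is part of each difference between the days. The streak is the transient structure from which mesoderm and endoderm arise, and its regulators MIXL1 (341 CPM at day 2 and 3.68 at day 4), EOMES (184 and 4.65), MESP1 (171 and 5.89) and LHX1 (254 and 5.86) were 29- to 92.5-fold lower at day 4. The secreted signals CER1 (226-fold), FGF4 (155-fold), FGF17 (62.3-fold) and the Notch ligand gene DLL3 (28.4-fold) were lower too, with CYP26A1 (25.6-fold), NTS (32.7-fold) and CDA (19.8-fold). DKK4 had 108 CPM at day 2 and 1 count at day 4 (log2 ratio -11.97, interval -17.27 to -9.49). Higher at day 4 were genes of smooth and cardiac muscle (ACTA2 326-fold, TNNI1 239-fold, MYL4 181-fold), the cyclase subunit gene GUCY1A1 (901-fold), RGS4 (812-fold), HOXB5 (586-fold) and the hepatic and yolk sac apolipoprotein gene APOA1 (181-fold). LUM (at least 5950-fold by the floor), COL3A1 (at least 4200-fold), TECRL (at least 1660-fold) and the endoderm gene TTR (at least 1240-fold) had 0 counts at day 2. The low interval ends of their log2 ratios were 12.24, 11.74, 10.4 and 9.98, below the floor values of 12.54, 12.04, 10.7 and 10.28. RGS13 had 1 count there (log2 ratio 12.17, interval 9.69 to 17.47). The interval end nearest to 0 was a log2 ratio of 7.16 or more for the higher genes and -4.09 or less for the lower ones. In all, 232 genes were at least 2-fold higher and 118 at least 2-fold lower at day 4, of 3239 genes at 50 CPM or more (285 and 205 with totals without mitochondrial and ribosomal protein genes).

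Lists fixed in advance traced the same change. All 10 measured genes of the primitive streak list were at least 2-fold lower at day 4 without inhibitor (median log2 ratio -5.37), among them TBXT (24.7 and 0.242 CPM, 102-fold) and GSC (144-fold). All 10 measured contractile genes (median 6.24) and all 8 HOX genes (6.99) were at least 2-fold higher. Of the cardiac mesoderm and progenitor list 10 of 13 genes were higher (median 3.36), such as HAND1 (54.5 and 747 CPM), ISL1 (10.2-fold) and TBX5 (0 and 6.61 CPM, at least 92.7-fold), and 1, MESP1, was lower. The presomitic and paraxial list had 8 of 11 genes lower (median -2.32), among them RIPPLY2, MESP2 (31.1-fold) and TBX6 (25.9-fold). Pluripotency genes were lower in 8 of 10 cases (median -1.28), with POU5F1 going from 1060 to 243 CPM. Higher in median were the lateral plate (2.14), amnion and surface ectoderm (2.75), BMP response (1.32) and extracellular matrix (1.14) lists. WNT feedback targets were mixed: 3 higher, among them LEF1 (5.10-fold) and TNFRSF19 (6.12-fold), 4 lower, among them SP5 (5.34-fold), and 8 between (median -0.22).

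With 48 h of inhibitor the same start point led to 147 genes at least 2-fold above day 2 and 64 below, of 3123 (207 and 121 with totals without mitochondrial and ribosomal protein genes, 282 and 139 in mesoderm cells). The genes highest against day 2 were nearly all of the sarcomere and its regulators: MYH6 (1720-fold), TNNI1 (793-fold), MEF2C (371-fold), MYL4 (266-fold), TNNT2 (231-fold), TTN (193-fold), ACTA2 (91.9-fold), MYOCD (80.0-fold), ACTC1 (58.8-fold) and MYL7 (56.3-fold). COL3A1 was at least 721-fold higher, and HAND2 had 2 counts at day 2 (log2 ratio 10.19, interval 8.33 to 13.24). CER1 (659-fold), MIXL1 (203-fold), FGF4 (109-fold), FGF17 (92.1-fold), NTS (55.7-fold), the WNT target SP5 (26-fold), CDA (23.6-fold), MESP1 (22.2-fold), EOMES (21.6-fold), DLL3 (21-fold) and LHX1 (15.8-fold) were lower, and DKK4 had 1 count (log2 ratio -12.15, interval -17.45 to -9.67). The WNT feedback list, with a median of -0.22 without inhibitor, stood at -1.08 against day 2 with it, 7 of its 13 genes lower and 2 higher. Contractile genes were higher in 14 of 14 cases (median 7.02) and cardiac mesoderm and progenitor genes in 11 of 14 (median 3.54).

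**Figure D1:**
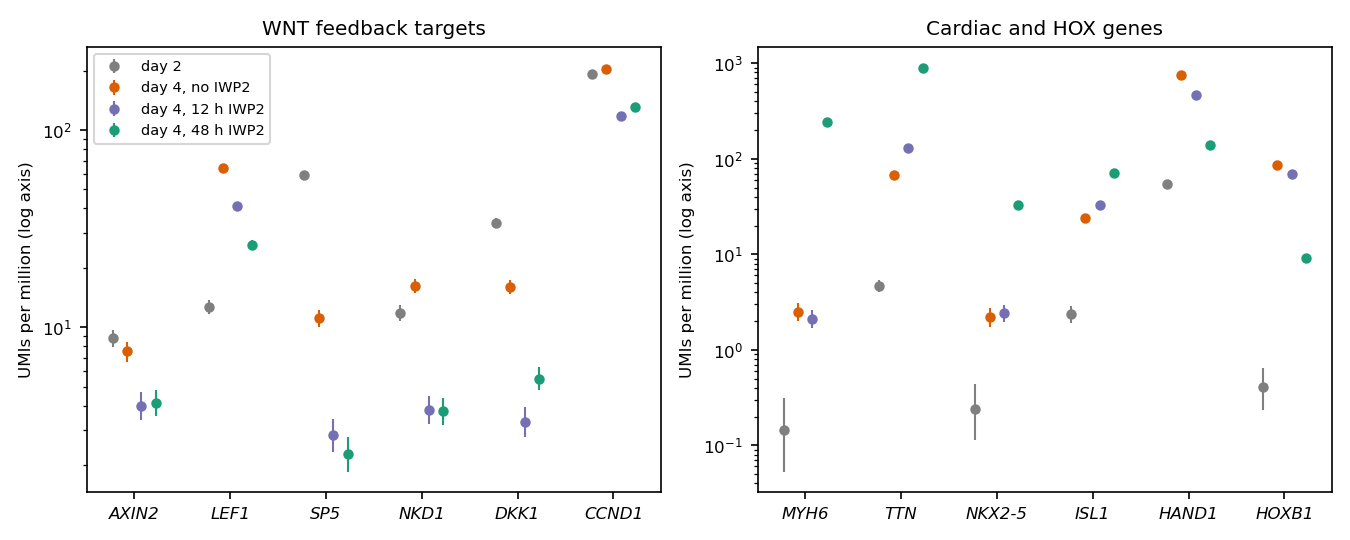
Level in CPM (UMIs per 1000000, log axis) of genes named in the text in the 4 libraries, with 95% Poisson intervals for counting error. MYH6 stands at 245 CPM after 48 h of IWP2 and at 2.5 and 2.12 CPM after 0 and 12 h, while HOXB1 goes from 86.8 through 69.9 to 9.07 CPM.

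Against the untreated day-4 library, 48 h of inhibitor came with higher sarcomere genes and lower HOX genes. MYH6, the myosin heavy chain of the early and atrial heart, was at 2.5 CPM without inhibitor and 245 CPM with it (97.9-fold, log2 ratio 6.61, interval 6.32 to 6.92), and TTN, the giant spring protein of the sarcomere, at 68.4 and 899 CPM (13.2-fold, log2 ratio 3.72, interval 3.66 to 3.78). MYOCD and MEF2C, transcription factors that switch on muscle genes, were 5.52-fold and 9.02-fold higher, with TNNI1 (3.32-fold), ANKRD1 (3.53-fold), PDLIM5 (4.15-fold), FILIP1 (8.15-fold) and the kinase gene DGKI (16.2-fold). The Notch ligand genes JAG1 (9.18-fold) and DLK1 (13.2-fold) and the semaphorin receptor gene NRP2 (3.31-fold) were also higher. Lower were the homeobox genes PRRX1 (83.6 to 3.93 CPM, 21.3-fold), PITX1 (13.0-fold) and MSX1 (9.86-fold), which mark limb and body-wall mesoderm, HOXB1 (9.58-fold) and HOXB5 (8.68-fold), which give axial position, MAB21L2 (8.21-fold), the matrix genes LUM (9.22-fold) and DDR2 (9.07-fold), and RGS13 (53.1-fold). The metal-binding metallothioneins MT1G (63.8-fold) and MT2A (23.7-fold), which were at 0.832 and 4.56 CPM at day 2, and the endoderm gene APOA1 (7.55-fold) were lower as well. The interval end nearest to 0 was 1.67 for the higher genes and -2.84 for the lower. Of 3157 genes at 50 CPM or more, 51 were at least 2-fold higher and 64 at least 2-fold lower. The balance depended on the cells and totals used: the counts were 83 and 78 with totals without mitochondrial and ribosomal protein genes, 93 and 80 in mesoderm cells with the unnamed clusters kept, and 136 and 93 in the cardiac and lateral plate cells alone.

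Among the lists, contractile genes were highest in count: 9 of 14 were at least 2-fold higher with 48 h of inhibitor and none lower (median log2 ratio 1.61, order-statistic interval over members 0.55 to 3.99, percentile 100 of the random lists). SLC8A1 (15.8-fold), PLN (4.11-fold), RYR2 (3.76-fold) and TNNT2 (2.42-fold) were higher, CSRP3 had 0 counts without inhibitor (at least 96.0-fold), and MYL7 was at 938 and 881 CPM. The cardiac mesoderm and progenitor list was split: NKX2-5 (2.18 to 32.8 CPM, 15.1-fold), MEF2C, MYOCD and ISL1 (2.91-fold) were higher, HAND1 (747 to 141 CPM, 5.31-fold) and GATA5 (2.11-fold) lower, and 8 between, such as GATA4 and TBX5 (median 0.35, percentile 100). The order-statistic interval over the members of this list, -0.25 to 2.47, held 0. The lateral plate list had 3 genes higher, among them BMP2 (2.63-fold) and IRX3, 4 lower (PRRX1, FOXF1 5.63-fold, HAND1, BMP4 2.35-fold) and 3 between (median -0.13, percentile 15.2). All 8 HOX genes were lower (median -2.98, percentile 0.00), HOXB2 by 2.08-fold, and both measured genes of the epicardium and juxtacardiac field list, MAB21L2 and TCF21, were lower (median -2.34, percentile 0.27).

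Genes of other cell types moved as well. All 5 measured neural ectoderm genes were higher (median 3.19, percentile 100), SIX3 by 35.6-fold, SOX21 by 12.8-fold, PAX6 by 9.13-fold and OTX2 by 3.47-fold. Against day 2, all 4 measured genes of this list were lower without inhibitor (median -2.61). With 48 h of it, 2 of 5 were higher than at day 2 and 3 between (median -0.07, percentile 22.5). Pluripotency genes had SOX2 2.79-fold higher and 7 between (median 0.54, percentile 100). The primitive streak list (median 1.16, percentile 99.8) had FGF8 (11.2-fold) and LHX1 higher, SP5 lower and 1 between. In the presomitic and paraxial list (median 0.43, 0.40 to 2.41 over alternatives, percentile 98.8) RIPPLY1 (39.1-fold), FOXC2 (5.35-fold) and FOXC1 (2.83-fold) were higher, CDX2 (27.4-fold) lower and 3 between. Definitive endoderm genes had HHEX higher (7.22-fold), 3 lower, TTR by 2.75-fold, and 5 between (median -0.68, percentile 0.00). Amnion and surface ectoderm genes had KRT7 lower (3.27-fold) and 5 between (median -0.37, percentile 0.52), and endothelium and blood had ETV2 lower (2.28-fold) and 2 between (median -0.22, percentile 16.3). Extracellular matrix genes were lower in 5 of 17 cases, COL3A1 by 5.83-fold and POSTN by 9.20-fold, and higher in none (median -0.56, percentile 0.00). Order-statistic intervals over members held 0 for the primitive streak (-2.28 to 3.49), definitive endoderm (-1.16 to 0.81) and amnion and surface ectoderm (-0.56 to 0.78) lists.

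The medians of the other signalling lists, without those of the WNT pathway, and of the cell cycle and stress lists at 48 h lay between -0.29 and 0.29. Notch pathway genes had 3 higher, JAG1, HES4 (3.04-fold) and HEY1 (2.32-fold), and 4 between (median 0.26, percentile 96.2), and FGF and ERK response genes had SPRY1 (2.81-fold), SPRY4 (2.11-fold) and DUSP5 (3.12-fold) higher and 8 between (0.29, 98.8). Of the retinoic acid list CYP26A1 was higher (3.63-fold) and 5 between (-0.22, 5.41), and of the BMP response list MSX1 and MSX2 (2.24-fold) were lower and 7 between (-0.03, 59.4). No member of the epithelium and cell transition (0.01, 65.0), S phase (0.04, 91.7), G2 and M phase (-0.29, 0.06), p53 (-0.03, 42.4) and unfolded protein (-0.11, 24.7) lists was 2-fold apart, and none of the cholesterol synthesis list (-0.23, 1.67). Hypoxia and glycolysis had 1 gene higher and 11 between (-0.09, 27.3), and immediate early and heat shock 1 lower and 10 between (-0.07, 29.9).

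**Figure D2:**
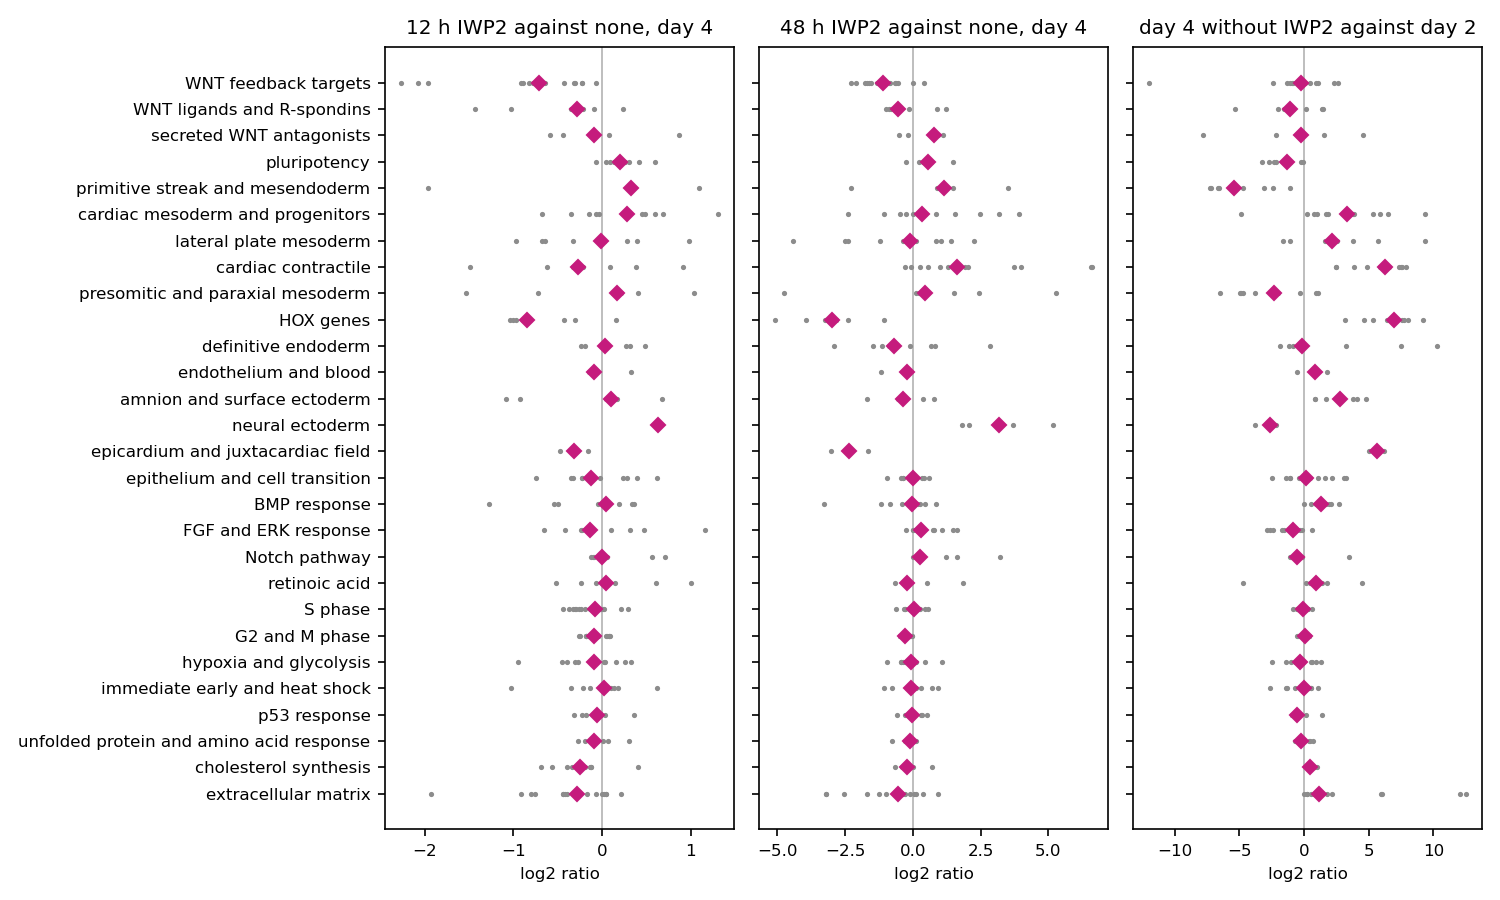
Log2 ratio of the members of the 28 gene lists (grey points) and their median (diamond) for 12 h of IWP2 against none, 48 h against none, and day 4 without IWP2 against day 2, on axes of different range, with members at 0 counts in 1 library drawn at the bound from a floor of 3 counts. WNT feedback targets have medians of -0.71, -1.10 and -0.22, and HOX genes of -0.85, -2.98 and 6.99.

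WNT feedback targets, which cells switch on when the pathway is active, were lower after both durations of the inhibitor. At 48 h 7 of 14 were at least 2-fold lower and none higher (median -1.10, order-statistic interval over members -1.70 to -0.56, percentile 0.00), and at 12 h 3 of 14 were lower (median -0.71, percentile 0.00). SP5 stood at 11.1 CPM without inhibitor, 2.83 after 12 h and 2.27 after 48 h, NKD1 at 16.2, 3.82 and 3.74, and DKK1 at 16.0, 3.31 and 5.49. AXIN2 (7.53, 4.00 and 4.14) was 1.88-fold lower after 12 h and 1.82-fold lower after 48 h. LEF1 (64.4, 41.2 and 26), RNF43 (7.50, 4.26 and 2.20) and LGR5 (10.4, 7.72 and 3.20) were lower at 48 h than at 12 h. MYC was 1.32-fold higher at 48 h. WNT ligand and R-spondin genes had a median of -0.54 at 48 h (percentile 0.48), with WNT5A (2.34-fold) higher and 7 between, and -0.28 at 12 h (percentile 1.10), with WNT4 (2.70-fold) and WNT5B (2.04-fold) lower. Secreted WNT antagonists had a median of 0.76 at 48 h (percentile 100), with SFRP1 (214 to 461 CPM) higher and 4 between, and of -0.09 at 12 h (percentile 42.6). At 48 h the order-statistic intervals over members held 0 for the ligands and R-spondins (-0.88 to 1.23) and for the antagonists (-0.53 to 1.11). At 12 h that of the ligands and R-spondins (-1.03 to 0.24) did too. Within clusters, the median of the WNT feedback list was below 0 in all 7 clusters with 50 cells in both libraries: -1.28 to -0.35 at 48 h and -1.32 to -0.36 at 12 h, with 4 to 12 genes measured per cluster at 48 h. All clusters share the same untreated library, and a deviation of it would also give such agreement, so the clusters are not replicates.

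After 12 h of inhibitor few genes were apart from the untreated library. The genes named as higher code for small mitochondrial proteins, some of them subunits of the respiratory chain: NDUFA3 (33.1 to 95.3 CPM, 2.88-fold), PET100 (2.76-fold), ROMO1 (2.69-fold), NDUFB1 (2.67-fold), ATP5ME (2.49-fold), NDUFA1 (2.49-fold), COX17 (2.45-fold) and SLIRP (2.35-fold). Of the 35 genes at least 2-fold higher, 19 were also at least 2-fold higher at day 2 than in the untreated day-4 library, and 17 of the 34 with a known transcript length had transcripts up to 700 nt, against 111 of all 3074 genes compared. Lower were MT2A (3.48-fold) and MT1G (2.81-fold), the homeobox genes PITX1 (2.96-fold) and MSX1 (2.43-fold), the smooth muscle actin gene ACTA2 (464 to 175 CPM, 2.66-fold) and PMP22 (2.08-fold), 6 genes in all at 2-fold or more, and SLC2A3 and FST, both 1.93-fold. The interval end nearest to 0 was 1.19 for the higher and -0.89 for the lower genes named.

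Among the lists at 12 h, HOX genes had a median of -0.85 (percentile 0.00), with 2 of 8 at least 2-fold lower, and extracellular matrix genes of -0.28 (percentile 0.03). Contractile genes had a median of -0.27 (percentile 0.49), with NPPB 2.81-fold lower, TTN 1.89-fold higher and 9 of 10 within 2-fold. Cardiac mesoderm and progenitor genes had a median of 0.28 (percentile 100), with MEF2C 2.47-fold higher and 12 within 2-fold. NKX2-5 was at 2.18 CPM without inhibitor and 2.42 after 12 h, a difference not detectable at this depth. The lateral plate (-0.01), definitive endoderm (0.04) and BMP response (0.05) medians lay within 0.1 of 0, and the paraxial median was 0.17 (percentile 90.0), over 6 genes with RIPPLY1 under the minimum level.

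The libraries after 48 h and 12 h of inhibitor differed in muscle, neural ectoderm and HOX genes, among others. MYH6 (2.12 to 245 CPM, 116-fold), TTN (6.96-fold), DGKI (6.94-fold), FILIP1 (6.54-fold), JAG1 (5.62-fold), DLK1 (5.27-fold), TNNI1 (3.84-fold) and PDLIM5 (3.84-fold) were higher at 48 h. RGS13 (27.8-fold), HOXB1 (7.71-fold), APOA1 (6.42-fold), LUM (4.88-fold), IGFBP6 (4.31-fold), MSX1 (4.06-fold), PLAT (3.86-fold) and PCAT14 (3.47-fold) were lower, although IGFBP6 and PCAT14 were higher at 48 h when the cardiac and lateral plate cells were compared alone. Of 3002 genes, 26 were at least 2-fold higher and 28 lower (61 and 28 in mesoderm cells, 90 and 48 in cardiac and lateral plate cells alone). Contractile genes were higher in 11 of 14 cases (median 1.5), neural ectoderm genes in 4 of 5 (2.38), and HOX genes lower in 6 of 6 (-2.09). WNT feedback targets had a median of -0.25, with 1 of 9 lower, cardiac mesoderm and progenitor genes of 0.07 (0.04 to 0.54 over alternatives), and paraxial genes of 1.06 (0.19 to 2.72).

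Across the 3183 genes at 50 CPM or more in a day-4 library, the log2 ratios at 12 h and 48 h against the untreated library had a Pearson r of 0.703 and a Spearman rho of 0.820. Both share that library, which alone gave an r of 0.524 in simulated libraries without differences, and how much of the excess also comes from it cannot be told with 1 library. The covariance was 0.106, against 0.000578 in the simulations. Genes are not independent replicates. At least 2-fold higher at both times were 17 genes (38 at 12 h and 51 at 48 h), and 6 were lower at both (6 and 64). Of the 51 genes higher at 48 h 47 lay on the same side of 0 at 12 h, and of the 64 lower ones 63 did. A deviation of the untreated library alone would also give such agreement, so these counts do not show a shared response. The 12 h library is a separate culture and the genes were chosen on their 48 h ratio. Their log2 ratio at 12 h divided by that at 48 h had a median of 0.331 (quartiles 0.134 and 0.84) for the higher and 0.341 (0.247 and 0.464) for the lower genes.

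**Figure D3:**
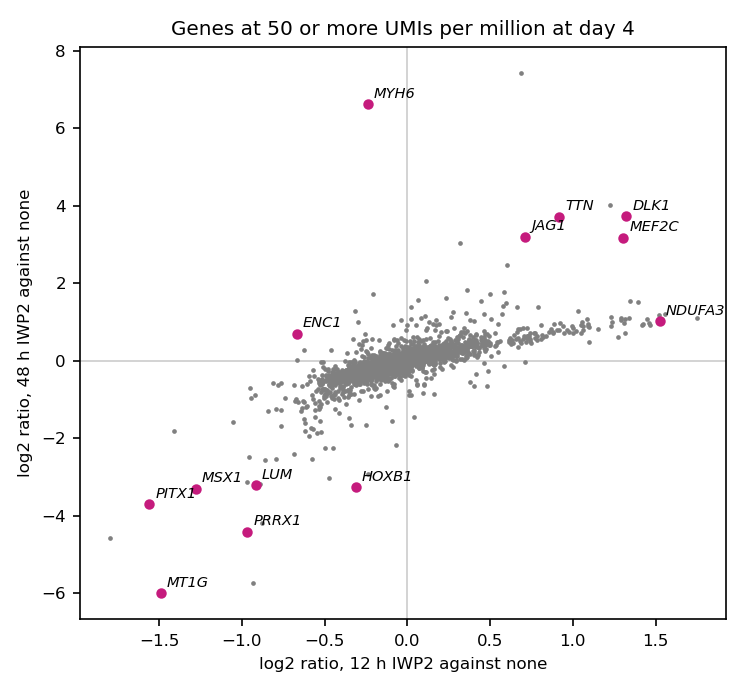
Log2 ratio of each of 3183 genes after 12 h of IWP2 (horizontal) and after 48 h (vertical), each against the same untreated day-4 library. Across genes r is 0.703, against 0.524 in simulated libraries that share a control and do not differ.

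Cells of day 4 fell into cardiac and lateral plate mesoderm-like, pluripotent-like, neural ectoderm-like and endoderm-like classes and unnamed clusters. Clustered without the genes that differed between the day-4 libraries, the cardiac and lateral plate class made up 55.7% of cells at 0 h (95% interval 53.7 to 57.7), 48.4% at 12 h (46.7 to 50.1) and 36.9% at 48 h (35.0 to 38.9). Within it, the cluster led by MYH6, TTN and NKX2-5 went from 6.23% (156 of 2506 cells) and 13.2% (437 of 3307) to 23.4% (553 of 2363). MYH6 itself was seen in 2.95% of cells at 0 h and 1.87% at 12 h without thinning, and in the clustering of all 4 libraries the MYH6-led cluster 10 held 0.20% (5 cells), 0.514% (17) and 32.0% (757) of the same libraries. At 48 h it held 26.9% with thinned cells and 19.1% at a minimum of 2000 genes, and since nearly all its cells are of 1 library it is not shown to be a cell type. In the clustering without differing genes, the clusters led by PLAT, NPPB and LUM (29.8, 24.0 and 8.59%) and by FGF19 and HOXB7 (19.6, 11.1 and 4.91%) were smaller at 48 h. Neural ectoderm-like cells made up 5.75, 7.14 and 16.8% (interval at 48 h 15.3 to 18.4), pluripotent-like cells 13.0, 17.4 and 21.1% (19.5 to 22.8) and endoderm-like cells 10.5, 12.5 and 3.98% (3.23 to 4.85). A class named streak-like from EOMES, MESP1, LHX1 and APLNR, and led by GYPB and RIPPLY1, made up 4.91, 8.47 and 12.7% (11.3 to 14.1) in this clustering alone. In the clustering of all 4 libraries the streak-like shares at day 4 were 0.12, 0.0302 and 0%, and the cluster led by SPOCK3, RIPPLY1 and GYPB had no class name. In the clustering of all 4 libraries, the cardiac class lay mostly in clusters 8 and 9 at 0 h (642 and 774 of 1421 cells) and 12 h (968 and 563 of 1548), and in cluster 10 at 48 h (757 of 936). At day 2 29.5% of cells were streak-like, 9.09% pluripotent-like, 2.27% neural ectoderm-like and 59.1% in clusters without a class name. With cells thinned before clustering these shares were 26.4, 14.7, 20.8 and 38.1%, so the neural ectoderm-like share at day 2 depends on the clustering. Shares are of cells that survived freezing, thawing, the live-cell sort and the gene minimum, and median depth differed between libraries (13882.5, 10809 and 15704 UMIs per cell).

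**Figure D4:**
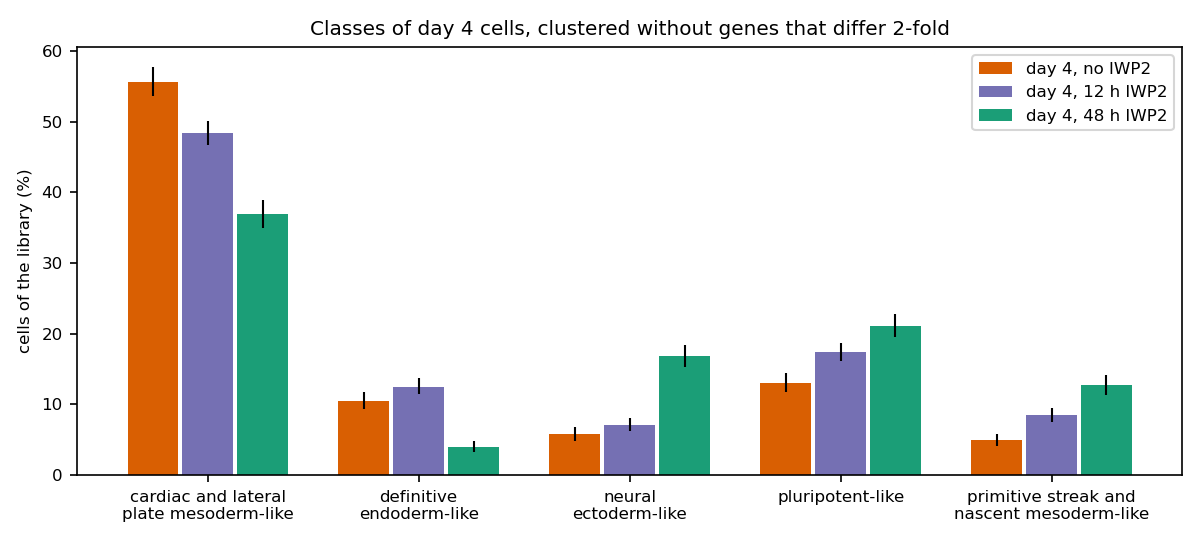
Share of cells (percent) in each class in the day-4 libraries, with 95% Clopper-Pearson intervals, from the clustering without genes at least 2-fold apart between day-4 libraries. Class names came from the full marker lists, which hold some of those genes. Cardiac and lateral plate mesoderm-like cells make up 55.7, 48.4 and 36.9% after 0, 12 and 48 h of IWP2, and neural ectoderm-like cells 5.75, 7.14 and 16.8%. In the clustering of all 4 libraries the streak-like class holds 0.12, 0.0302 and 0% of these cells.

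Shares of cells with a UMI of single markers, with every cell thinned to 5000 UMIs, are given beside the share in a class that should lack the gene. That background share is also of thinned cells unless called unthinned, and it is higher for most genes without thinning. NKX2-5 was seen in 0.768% of cells at 0 h (interval 0.463 to 1.2), 0.894% at 12 h (0.599 to 1.28) and 11.3% at 48 h (10.0 to 12.6), with 0, 0 and 0.418% of pluripotent-like cells. Without thinning the shares were 2.27, 2.21 and 20.4%. MYH6 was seen in 1.01, 1.08 and 21.9% (background 0, 0 and 0.626%, unthinned 2.95, 1.87 and 29%), ISL1 in 10.0, 13.4 and 25.1% (background 2.07, 1.71 and 0.418%, unthinned 21, 23.2 and 41.3%) and HAND1 in 59.0, 49.6 and 25.8% (background 5.86, 4.94 and 1.04%, unthinned 64.6, 55.7 and 36.2%). TNNT2 was seen in 42.5, 37.4 and 39.4% of cells (background 8.62, 8.37 and 7.72%, unthinned 57.6, 49.0 and 52.7%) while its level in the summed counts was 200, 161 and 484 CPM. POU5F1 was in 22.8, 32.2 and 35.3% (cardiac class 6.18, 11.2 and 10.2%, unthinned 34.3, 44.0 and 52.6%) and SOX17 in 6.35, 5.70 and 2.56% (cardiac class 0.213, 0 and 0.215%, unthinned 8.26, 7.56 and 3.94%). Without thinning POU5F1 was in 15.8, 21.8 and 26.6% of the cardiac class. The median depths were 18029, 15328 and 20684 UMIs in pluripotent-like cells and 13705, 9749 and 13087 in the cardiac class. At day 2 MESP1 was seen in 29.3% of cells, HAND1 in 12.0%, TBXT in 8.24% and TBX6 in 7.90% (pluripotent-like cells 0, 0, 0 and 1.25%, unthinned 39.9, 20.9, 22.3 and 24.5%).

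Within the cardiac clusters compared, the 48 h and untreated libraries were nearer in contractile and HOX genes than as whole libraries. The clustering did not leave these genes out: HOX genes are among the leading genes of clusters 8 and 9, and MYH6 and TTN lead cluster 10. A smaller gap within clusters 8 and 9 was thus largely set by the clustering, and no conclusion is drawn from it. In clusters 8 and 9 of the cardiac class the contractile median was 0.84 (6 of 13 genes higher) and 0.67 (3 of 10 higher, 1 lower), against 1.61 in the whole library, and the HOX median -0.58 (1 of 6 lower) and -0.54 (1 of 9 lower, 1 higher), against -2.98. In the unnamed cluster 7 the HOX median was -1.88 (3 of 4 lower). In clusters 8 and 9 the extracellular matrix medians were -0.12 and -0.07. At 12 h the contractile medians in these clusters were -0.02 and -0.03. Notch pathway genes had medians of 1.42 and 1.57 in clusters 8 and 9 (5 and 6 genes) and of 1.43 in the endoderm-like cluster (7 genes), and of -0.14 to 0.44 in the other 4 clusters compared. In the neural ectoderm-like cluster all 6 measured neural genes were at least 2-fold higher at 48 h (median 2.22), while amnion and surface ectoderm genes (median -1.11, 5 of 8 lower) and retinoic acid genes (-1.84, 5 of 6 lower) were lower. At resolution 1.0 an amnion and surface ectoderm-like cluster of 42, 48 and 83 cells at 0, 12 and 48 h was separate from a neural ectoderm-like cluster of 90, 186 and 331, so a shift in the mix of cells within the cluster is not excluded. Clusters 8 and 9 held 90 and 89 cells at 48 h, so that most cardiac cells of that library are not in this comparison.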

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

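Most tests in this part were chosen only after the results were seen: all of those for HHEX, NKX2-5 and the metallothioneins, and for the short transcripts the comparisons with ribosomal protein genes and between libraries. The test of other short transcripts was written before its result was seen.

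One gene at 50 CPM or more, ENC1, was at least 1.5-fold apart from the untreated day-4 library in opposite directions after the 2 durations of inhibitor. Its log2 ratio was -0.67 after 12 h and 0.70 after 48 h (55.4, 34.8 and 90.0 CPM after 0, 12 and 48 h). The difference was not tested. The contractile list moved in opposite directions within 2 clusters at 48 h: its median log2 ratio was -1.35 in the neural ectoderm-like cluster (4 of 6 genes at least 2-fold lower) and 2.06 in the endoderm-like cluster (7 of 8 higher, 1 lower). That difference was not tested either. MYH6, ACTC1 and TTN stood in the endoderm-like cluster at 1.54, 2.23 and 3.94% of their level in the MYH6-high cluster, so free RNA or doublets from cardiac cells may account for the contractile genes there.

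Oxidative phosphorylation and other short transcripts were lower in the untreated day-4 library than after 12 h of inhibitor. Over genes with transcripts of 1000 to 3000 nt, the excess at 12 h was 0.25 in log2 for 79 oxidative phosphorylation genes, 0.21 for 83 other genes with transcripts up to 700 nt, and 0.34 for 83 ribosomal protein genes, which argues against a response limited to oxidative phosphorylation. Weaker capture of short transcripts in that library met the bound set for it in advance (0.21 against 0.25), yet oxidative phosphorylation genes still exceeded genes of matched length by 0.19 (interval 0.06 to 0.40), so it cannot be told apart from a change of these genes themselves. Across the other genes at 20 CPM or more with a known length, ribosomal proteins left out, longer transcripts were the higher ones against the untreated library at 12 h (Spearman 0.11) and 48 h (0.19), and shorter ones at day 2 (-0.11). Trends as large stood between libraries without the excess (0.21 for 48 h against 12 h and -0.18 for day 2 against 12 h), so they decide nothing about the untreated library. Within clusters at 12 h, the excess of the other short genes (0.25 to 0.35) was above that of oxidative phosphorylation genes (0.19 to 0.29) in 4 of 7 clusters. At 48 h it was above only in cluster 7 (0.28 and 0.27) and cluster 8 (0.33 and 0.31). It was lower or equal in the others, such as the endoderm-like cluster (0.12 and 0.35). All clusters share 1 untreated library, so these near-even splits decide nothing. The excess of 0.19 over matched length also met the bound first set for the limited response, and the comparison with ribosomal proteins was added after seeing it. Over genes of 1000 to 3000 nt, the excess of oxidative phosphorylation genes was 0.29 for day 2 against the untreated day-4 library. It was -0.02 for 48 h against 12 h and -0.01 for day 2 against 12 h. These values go with a peculiarity of the untreated library and leave open its preparation and its biology.

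HHEX and NKX2-5, genes of foregut and heart, were higher in the endoderm-like cluster after 48 h of inhibitor (HHEX 12.4, 31.4 and 171 CPM, NKX2-5 2.78, 3.01 and 32.4 CPM after 0, 12 and 48 h). NKX2-5 stood there at 36.0% (interval 28.3 to 45.3) of its level in the MYH6-high cluster. TTN, the highest of 3 muscle genes, reached 3.94%, ACTC1 2.23% and MYH6 1.54%. Free RNA or doublets from MYH6-high cells would bring these muscle genes along, so such a source alone falls short of the NKX2-5 level. Sources of NKX2-5 outside that cluster were not tested. At 48 h an NKX2-5 UMI was seen in 10.8% of thinned endoderm-like cells and 11.3% of the other cells. The highest HHEX level in any other cluster of that library was 5.10 CPM, which argues against an outside source of HHEX. Loss of other endoderm-like cells alone is argued against by the share of all cells that were endoderm-like with an HHEX UMI, 0.607% without inhibitor and 2.05% at 48 h, a ratio of 3.38. For NKX2-5 these shares were 0.162% (4 cells, interval 0.0441 to 0.414) and 0.555% (13 cells, 0.296 to 0.947), a ratio of 3.43 (1.06 to 14.4), too few cells to exclude such a loss. A change of identity within the endoderm-like cells may remain as a hypothesis for HHEX, with the inhibitor and differences between cultures confounded in 1 library each.

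Metallothioneins were lower after 12 and 48 h of inhibitor than without it in each of 7 clusters (median log2 ratio of 6 genes from -1.05 to -3.96 at 12 h and from -2.72 to -4.97 at 48 h). Genes at 0 counts entered at 3 counts, so these medians can understate the fall: the summed level in the endoderm-like cluster went from 96.0 to 6.23 and 0.82 CPM, with a median of -3.14 at 48 h. Free RNA from pluripotent-like cells, where their summed level was highest (758, 247 and 20.3 CPM), carries its genes in 1 ratio, but in the untreated lateral plate clusters the pluripotency gene TDGF1 reached 0.274% of its pluripotent-like level and the lowest metallothionein, MT1X, 8.69%. A first version of this test, by the list median, had favoured free RNA (9.99% for pluripotency genes and 17.6% for metallothioneins) and was replaced after its value was seen, since some pluripotency genes such as LIN28A are also made outside that class. Fewer metallothionein-high cells at 48 h go with part of the fall: at resolution 1.0 the pluripotent-like cells part into a cluster led by MT1X, MT1G and MT1H (256, 358 and 88 cells after 0, 12 and 48 h), one without them (42, 174 and 385 cells) and another, mostly of day 2 (7, 8 and 1 cells). As the whole explanation this is argued against by the median log2 ratio at 48 h within the metallothionein-led cluster itself, -4.03 (summed level 858 and 43.5 CPM), beside -4.97 in all pluripotent-like cells, the value first used for this test. The other clusters had too few untreated cells to compare. Whether the inhibitor, or a difference in the medium or metal supply of the untreated culture, underlies it was not tested, and day 2 was low as well.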

How the results depend on the processing

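Comparisons of the cardiac and lateral plate cells alone, the clustering without differing genes and the extended rule for naming clusters were chosen after the data had been seen. No paired analysis was possible because each group had 1 library.

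List medians for WNT feedback, cardiac and paraxial genes stayed within their interval in 116 of 116 alternatives, with WNT feedback from -1.14 to -0.95 at 48 h, -0.71 to -0.41 at 12 h and -0.30 to -0.23 between them. That interval spans the members of a list and is wide, so staying inside it shows little. Cardiac mesoderm and progenitor medians ranged from 0.31 to 0.88 at 48 h, 0.26 to 0.47 at 12 h, 0.04 to 0.54 between them and 1.77 to 3.36 for 0 h against day 2. Paraxial medians ranged from 0.40 to 2.41, 0.09 to 0.37, 0.19 to 2.72 and -4.76 to -2.22, and WNT feedback from -0.57 to -0.21 for 0 h against day 2. At 20 CPM no paraxial gene was left for 12 h against 0 h, so that alternative gave no value. Counts of genes stayed within 1.5-fold in 68 of 96 alternatives. No scaling shifted the median of all genes by over 0.1.

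A minimum of 20 or 100 CPM changes the number of genes compared by construction. At 20 CPM the counts higher and lower were 115 and 122 for 48 h against 0 h, 70 and 56 for 48 h against 12 h, 461 and 263 for 0 h against day 2 and 337 and 172 for 48 h against day 2, with 17 lower for 12 h against 0 h. At 100 CPM they were 26 and 36, 12 and 12, 116 and 70, and 70 and 37, with 2 lower for 12 h against 0 h. With totals without mitochondrial and ribosomal protein genes, 83 were higher for 48 h against 0 h, 205 lower for 0 h against day 2 and 121 lower for 48 h against day 2. In mesoderm cells only (unnamed clusters kept), 93 were higher for 48 h against 0 h, 61 higher for 48 h against 12 h, and 282 higher and 139 lower for 48 h against day 2. In cardiac and lateral plate cells alone, 136 were higher for 48 h against 0 h, and 90 higher and 48 lower for 48 h against 12 h. For these settings the cause was not tested.

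Class shares from the clustering of all libraries (56.7, 46.8 and 39.6% cardiac after 0, 12 and 48 h) stayed within their interval in 42 of 57 alternatives. At resolution 1.0 the pluripotent-like share at day 2 was 14.5%, the streak-like share at day 2 25.2%, and neural ectoderm-like shares 3.59, 5.62 and 14.0% after 0, 12 and 48 h. With thinned cells, day 2 had 14.7% pluripotent-like, 20.8% neural ectoderm-like and 26.4% streak-like cells, and 48 h 35.3% cardiac cells. At a minimum of 2000 genes cardiac shares were 53.4, 44.2 and 27.0%, and the streak-like share at day 2 26.2%. Without differing genes, 48 h had 3.98% endoderm-like and 36.9% cardiac cells. The cause was not tested.

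Log2 ratios of named genes moved beyond counting error in 151 of 784 alternatives and reversed in 4. Most moved once the cells were restricted: 67 of 104 moved in mesoderm cells only and 43 of 56 in cardiac and lateral plate cells alone, beside 33 of 104 with the mean over cells and 0 of 104 with all barcodes or doublets kept. The reversals were all for 48 h against 12 h: IGFBP6 (0.18) and PCAT14 (0.83) in mesoderm cells only, and IGFBP6 (0.23) and PCAT14 (1.75) in cardiac and lateral plate cells alone, where the cause was not tested. Shares of cells with a marker UMI moved in 93 of 112 alternatives, since no thinning or a minimum of 2 UMIs changes detection by construction. The correlation of the 12 h and 48 h ratios was 0.712 at 20 CPM and 0.707 at 100 CPM. Depth limits genes under the list minimum of 5 CPM and shares near the background class.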

Other observations

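An unnamed cluster of the day-4 libraries (224, 163 and 132 cells after 0, 12 and 48 h of inhibitor, and 1 cell at day 2) was led by SOX10, S100B and TFAP2B, genes of neural crest and glia. Lists of neural crest, Schwann cell lineage and melanoblast genes were written after its 10 leading genes had been seen and share members with them, so their levels are not independent of the cluster's definition. SOX10 was at 124, 131 and 128 CPM in the cluster and FOXD3 at 61.4, 34.9 and 73.6 CPM. Of the melanoblast genes, TYR had 0 counts in all 3, DCT 0, 0.634 and 0 CPM and MITF 1.09, 1.27 and 0.554 CPM. CDH19 of the Schwann cell list had 0 counts. Clustered without the genes that differed, the SOX10-led cells made up 9.14, 5.23 and 6.31% of the libraries.

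Another unnamed cluster, led by SPOCK3, RIPPLY1 and GYPB, held 123, 379 and 287 cells. At a minimum of 2000 genes per cell the cluster with these leading genes held 208, 467 and 581 cells (8.40, 14.5 and 24.7%), so its size depends on the clustering. By the count of markers alone it would have been named cardiac and lateral plate mesoderm-like, but none of its 10 leading genes belongs to that class and 1 belongs to another. At day 2 unnamed clusters held 343 cells led by PLA2G2A, IRX1 and OLIG3 and 696 cells led by CER1, DKK4 and LHX1.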
